A study of Mus musculus with 8 samples.

How the data were processed

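The samples were B cells positive for CD5 and CD19, isolated from the spleens of 8 leukaemic C57BL/6J mice that were killed at the end stage of disease. One Affymetrix array was hybridised per mouse, with 4 mice that carry a Tcl1 transgene (Tcl1 tg) and 4 that carry it together with an altered Cd44 gene, called CD44ΔB in the labels (CD44ΔB Tcl1 tg). The mice were different animals, per the series' design text, so the p-values measure the spread between mice. Total RNA was extracted with DNase digestion, turned into sense-strand cDNA, fragmented and biotin-labelled with a whole-transcript kit, per the labels' protocols. The deposited values are log2 signals made by the authors with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. RMA corrects the background, normalizes probes between arrays so that their distributions match, and averages the probes of a gene into 1 value. The genome build and the annotation used upstream are not given in the sources used here, so no coordinates are printed.

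The table held 28846 features, with values from 1.17 to 13.56. A total of 6640 were control probe sets and were left out of the tests, and 22206 were transcript clusters, each a summary of the probes of 1 locus. Of these, 19572 had 1 gene symbol in the platform annotation and 2634 had none, and no cluster had several. All 19572 matched the gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. Where a symbol had several clusters, the one with the highest mean over the 8 arrays was kept, which left 19505 symbols. Genes whose mean over the 8 arrays lay above the median of all transcript clusters (5.74) were tested, 10001 in all. Cd19 and Cd38 had no named cluster, and Zap70 and Tcl1 fell below this filter.

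Differences between the genotypes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with the genotype as the only term, and are given as CD44ΔB Tcl1 tg minus Tcl1 tg on the log2 scale. P-values were adjusted by Benjamini-Hochberg over the 10001 genes, with a threshold of 0.05. Values are given as mean ± SD over 4 mice. For single values, an exact two-sided permutation test over the 70 ways to pick 4 of 8 arrays was used, whose smallest possible p-value is 0.0286. The number of arrays limits the precision. Gene lists (31, fixed before the data were examined: pathways, B-cell states, other cell types and checks) were tested with limma's camera at a preset correlation between genes of 0.01 where at least 5 members were tested, 28 lists in all, adjusted over these 28. The test was repeated with a correlation estimated for each list, on ranks, and with fry, whose directional p-value asks whether the members of a list move one way on balance without comparing them with other genes. A list score is the mean over its tested members of the deviation from the Tcl1 tg mean.

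The named genes followed a rule fixed at the same time. It took Cd44, Cd19, Cd5, Itga4, Mcl1, Bcl2, Zap70, Cd38, Cxcr4, Myc, Mki67 and Tcl1 where measured. It took up to 12 genes in each direction past the adjusted threshold, filled up with the genes of smallest unadjusted p-value among those that differed at least 1.5-fold with no overlap between the groups. Immunoglobulin and T cell receptor segments, predicted genes, clones, small RNA genes and olfactory or vomeronasal receptors were left out there. It also took the members of smallest p-value in each list, 4 for lists past the threshold and 2 for the others. Only 7 genes met the rule on the higher side.

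The steps were tested on simulated data: log2 values for the 10001 genes were drawn with the measured means and variances, and 200 genes were shifted. With 4 arrays a group, 22 of 50 genes shifted 1.5-fold were recovered, 36 of 50 shifted 2-fold, 46 of 50 shifted 4-fold and 49 of 50 shifted 8-fold, with 6 unshifted genes called. The simulation drew genes independently, unlike those on real arrays. It also shifted 200 genes at once, which makes the Benjamini-Hochberg threshold easier to pass than where few genes differ. The recovered shares may therefore overstate what the real comparison could find.

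Alternatives covered the filter on dim genes, quantile normalization and median centring of the deposited values, the variance model, array weights, age in days as a covariate, the replicate number as a block, the rule for several clusters of 1 gene, the thresholds, the set test, and leaving out each array in turn. A fit without the 2 arrays of narrowest value range was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.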

Results

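The arrays compared leukaemic B cells of 4 Tcl1 tg mice with those of 4 CD44ΔB Tcl1 tg mice. Mice with a Tcl1 transgene in B cells develop an expansion of CD5-positive B cells that serves as a model of chronic lymphocytic leukaemia. CD44 is a cell-surface receptor for hyaluronan. The comparison addresses which transcripts of the leukaemic cells differ with the CD44ΔB alteration. The Tcl1 tg mice were 275 to 421 days old and the CD44ΔB Tcl1 tg mice 270 to 456 days old. The interquartile range of the log2 values lay between 3.76 and 3.87 on 6 arrays. It was narrower on CD44ΔB Tcl1 tg replicates 2 (3.54) and 3 (3.56). These 2 arrays also had the weakest separation of positive from negative control probe sets. Their areas under the curve were 0.880 and 0.870, against 0.894 to 0.910 on the others.

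Cd44 was the gene that differed between the genotypes. It stood at 10.96 ± 0.36 (SD, n = 4) in Tcl1 tg and at 8.31 ± 0.11 (SD, n = 4) in CD44ΔB Tcl1 tg cells. The difference was −2.66 on the log2 scale (SE 0.17) or 6.30-fold (limma, adjusted p = 0.00051). The 4 Tcl1 tg mice had values of 11.46, 10.99, 10.65 and 10.76, and the 4 CD44ΔB Tcl1 tg mice 8.42, 8.36, 8.25 and 8.18. The groups did not overlap (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). The remaining value of 8.31 lay above the filter on dim genes (5.74). The value averages the probes of the whole transcript cluster, and the labels do not say which part of the gene was altered. Without the 2 arrays of narrower range, which leaves 2 mice in that group, the difference was −2.66 with an adjusted p = 0.11. Over the 19 alternatives the adjusted p ran from 0.00021 to that value.

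**Figure D1:**
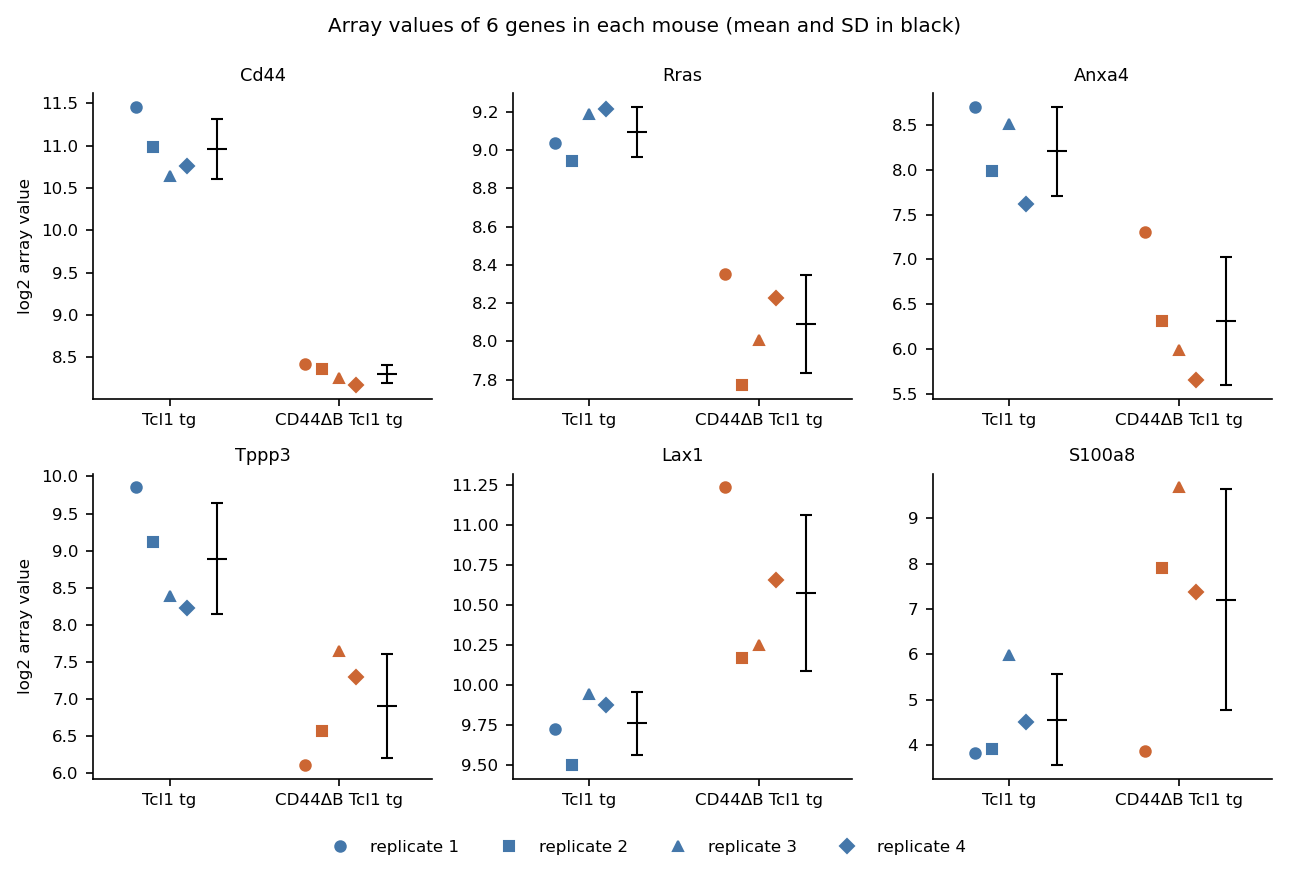
Log2 array values (vertical axis) of 6 genes in the 4 Tcl1 tg mice (blue) and the 4 CD44ΔB Tcl1 tg mice (orange); the marker shape gives the replicate number, and the black bars give the mean and SD of each group. Cd44 lies at 8.42 or below in all CD44ΔB Tcl1 tg mice and at 10.65 or above in all Tcl1 tg mice, while S100a8 varies from 3.88 to 9.67 among the CD44ΔB Tcl1 tg mice.

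No other gene passed. Of 10001 genes tested, 1 (Cd44) passed the adjusted threshold, and the next was Rras at an adjusted p of 0.31. At an unadjusted p under 0.05, limma listed 627 genes, against 500 that chance gives. Of these, 145 were higher and 482 lower in CD44ΔB Tcl1 tg cells. Single arrays moved these counts: 88 were higher and 318 lower without Tcl1 tg replicate 1, and 91 and 326 without Tcl1 tg replicate 2. Without CD44ΔB Tcl1 tg replicate 1 they were 263 and 787, without replicate 2 84 and 315, and without replicate 4 202 and 779. After quantile normalization of the deposited values the split at this level was 239 higher and 325 lower. A total of 366 genes (3.66%) showed no overlap between the groups, against the 2.86% that chance gives. Of the 366, 110 were higher and 256 lower. Leaving out Tcl1 tg replicate 3 gave 2 genes, Cd44 and Grk3. The latter, singled out after its values were seen, had an adjusted p of 0.026, against 0.76 with all 8 arrays. Leaving out both arrays of narrower range gave 0 with limma, with 148 genes higher and 214 lower at an unadjusted p under 0.05.

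The smallest p-value on the lower side after Cd44 was that of the small GTPase Rras, at 9.09 ± 0.13 in Tcl1 tg and 8.09 ± 0.25 in CD44ΔB Tcl1 tg cells (2.01-fold, adjusted p = 0.31). It was followed, among the named genes, by the membrane protein gene Myadm (log2 difference −0.72, SE 0.12, adjusted p = 0.41). The calcium-dependent phospholipid-binding protein gene Anxa4 had a log2 difference of −1.89 (SE 0.36, adjusted p = 0.65). Tppp3, which encodes a tubulin-binding protein, had one of −1.98 (SE 0.42), with values of 8.89 ± 0.75 and 6.91 ± 0.70. The others named on this side were Jph1 (−1.40), Dkkl1 (−1.12), Lilra6 (−0.95), the quinone reductase gene Nqo2 (−0.80), Hspb11 (−0.61) and the lipid droplet coat gene Plin3 (−0.60). The acyl-CoA thioesterase gene Acot7 was at 7.84 ± 0.40 and 6.84 ± 0.19. The 7 genes named on the higher side were Lax1 (0.81), an adaptor of lymphocyte receptor signalling, Ypel2 (0.66), Gramd2 (0.66), the inhibin subunit gene Inha (0.64), the retromer gene Vps26b (0.64), Cfap157 (0.63) and Setbp1 (0.59). The rule took these 18 genes only because the 4 mice of one genotype did not overlap the 4 of the other. The lack of overlap is thus no added support for them. Each missed the threshold, at adjusted p-values from 0.31 to 0.70 for the lower genes and 0.76 for the higher ones.

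**Figure D2:**
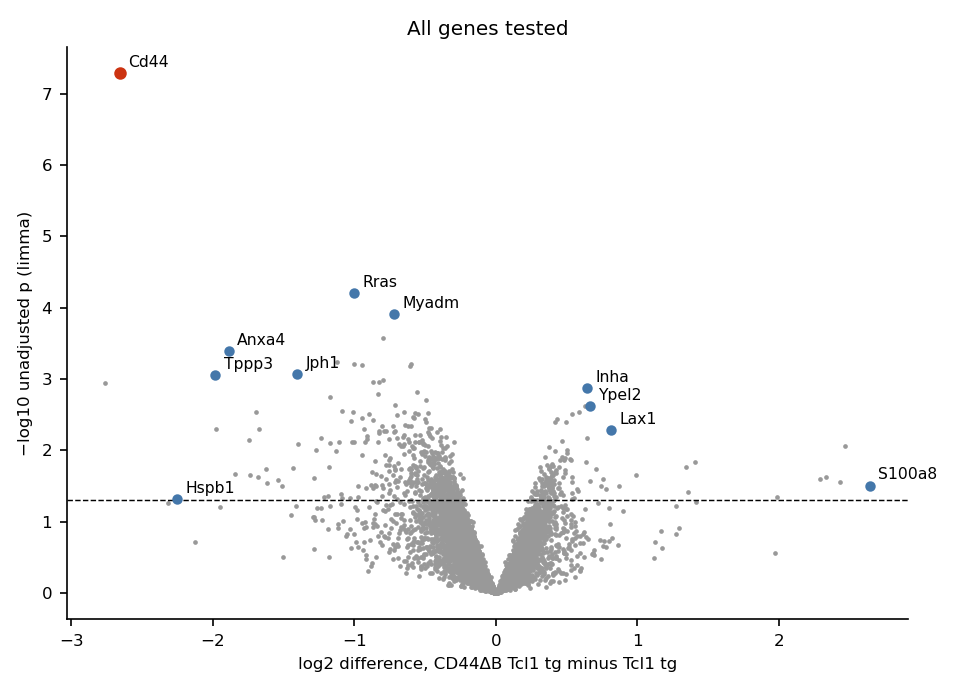
Log2 difference between the genotypes (horizontal axis, CD44ΔB Tcl1 tg minus Tcl1 tg) against the negative log10 of limma's unadjusted p (vertical axis) for each of the 10001 genes tested; the dashed line marks an unadjusted p of 0.05, red marks the 1 gene past the adjusted threshold, and blue marks other genes the text names. Cd44 stands apart from the rest at a difference of −2.66, with more of the other genes above the line on the lower side (482 with Cd44) than on the higher side (145).

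Of the genes chosen in advance for their place in leukaemic B cells, the lineage marker Cd5 was at 8.47 ± 0.35 in Tcl1 tg and 8.29 ± 0.35 in CD44ΔB Tcl1 tg cells. The survival genes Mcl1 (12.07 ± 0.10 and 12.25 ± 0.15) and Bcl2 (10.31 ± 0.41 and 10.35 ± 0.21), the integrin gene Itga4 (10.37 ± 0.27 and 10.19 ± 0.25), the homing receptor gene Cxcr4 (9.32 ± 0.88 and 9.89 ± 0.94) and Myc (11.55 ± 0.15 and 11.31 ± 0.17) also missed the threshold. The proliferation marker Mki67 had a log2 difference of −0.31 (SE 0.44). Adjusted p-values of these genes ran from 0.76 to 0.97. Zap70 (4.76 ± 0.45 and 4.89 ± 0.27) and Tcl1 (4.17 ± 0.29 and 3.91 ± 0.44) lay below the filter on dim genes in both genotypes. The labels give a Tcl1 transgene for all 8 mice, whereas the Tcl1 cluster read 3.48 to 4.61 over the 8 arrays. The cluster is named for the mouse gene, and the sources used here do not say whether its probes match the transgene. The low value would go against the labels only if the probes match, so it cannot test the labels.

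With a preset correlation, camera called 6 of the 28 gene lists tested, 4 toward lower and 2 toward higher values in CD44ΔB Tcl1 tg cells. With an estimated correlation it called 0 (adjusted p = 0.79 for each of the 6, and 0 lists at an unadjusted p under 0.05), and fry called 0 (1 list at an unadjusted p under 0.05). Cd44 is in none of the lists, and 0 of their members passed over all genes tested. Adjusted over the list alone, 5 members passed, 1 in the B-1 cell list and 4 in the neutrophil list. Of all 10001 genes tested, 5940 (59.4%) were lower in CD44ΔB Tcl1 tg cells, with a median log2 difference of −0.05. The counts of lower members given below are to be read against that share.

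The heat shock genes, which encode chaperones of the cytosol and mitochondria, were lower in all 12 members tested, with a median log2 difference of −0.67 (camera, adjusted p = 0.0051 with the preset and 0.79 with an estimated correlation). Hspb1 stood at 8.61 ± 2.28 in Tcl1 tg and 6.36 ± 1.00 in CD44ΔB Tcl1 tg cells, Dnajb1 at 11.07 ± 0.68 and 10.09 ± 0.66. Hspa1b was at 11.98 ± 0.68 and 11.00 ± 1.11, and Hspd1 at 10.72 ± 0.27 and 10.29 ± 0.42. The list score of single mice ranged from −0.83 to 0.60 in Tcl1 tg and from −1.40 to 0.15 in CD44ΔB Tcl1 tg cells. Single arrays moved the median: without CD44ΔB Tcl1 tg replicate 1 it was −0.34 and the call was lost (adjusted p = 0.24). It was −0.45 without Tcl1 tg replicate 1, −1.11 without CD44ΔB Tcl1 tg replicate 2, and −1.07 without both arrays of narrower range. Over the 22 alternatives the adjusted p ran from 5.4e-09 to 0.79.

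Antigen presentation genes of the MHC class II pathway were lower in 15 of 16 members, with a median of −0.20 (adjusted p = 0.0051 with the preset and 0.79 with an estimated correlation). H2-Aa, a chain of the class II molecule, was at 12.71 ± 0.15 in Tcl1 tg and 12.40 ± 0.16 in CD44ΔB Tcl1 tg cells. H2-DMa, which helps load peptide, was at 10.51 ± 0.21 and 10.11 ± 0.12. The costimulatory genes Cd40 and Cd80 had log2 differences of −0.45 and −0.38. The call was lost without Tcl1 tg replicate 3 (median −0.19, adjusted p = 0.051), CD44ΔB Tcl1 tg replicate 1 (median −0.16, adjusted p = 0.053) or replicate 4 (median −0.20, adjusted p = 0.086). Without both arrays of narrower range the median was −0.29. The adjusted p ran from 4.3e-05 to 0.79 over the 22 alternatives.

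Genes of oxidative phosphorylation were lower in 38 of 43 members, with a median of −0.18 (adjusted p = 0.0051 with the preset and 0.79 with an estimated correlation). Those of glycolysis and the hypoxia response were lower in 25 of 29, with a median of −0.17 (adjusted p = 0.030 with the preset and 0.79 with an estimated correlation). In the first list the complex I genes Ndufv2 and Ndufb6 had log2 differences of −0.62 and −0.48, the complex III gene Uqcrc1 −0.39 and the complex II gene Sdhb −0.29. In the second list Adm, a secreted peptide induced by low oxygen, was at 11.26 ± 0.66 in Tcl1 tg and 9.58 ± 0.93 in CD44ΔB Tcl1 tg cells. The glycolytic enzyme genes Aldoc, Pgam1 and Aldoa had log2 differences of −0.94, −0.43 and −0.38. Both calls were lost without the 2 CD44ΔB Tcl1 tg arrays of narrower range, where both medians were −0.06 (adjusted p = 0.25 and adjusted p = 0.22). The first was also lost without CD44ΔB Tcl1 tg replicate 2, with a median of −0.08 (adjusted p = 0.21), and without replicate 4, with a median of −0.16 (adjusted p = 0.059). After quantile normalization its median was −0.12 and the call was kept (adjusted p = 0.013). The second was lost after median centring (adjusted p = 0.053), and with a filter at the 75th percentile (adjusted p = 0.051). It was also lost without Tcl1 tg replicate 1 (adjusted p = 0.27) or 3 (adjusted p = 0.090), or CD44ΔB Tcl1 tg replicate 1 (adjusted p = 0.063) or 3 (adjusted p = 0.068), with medians from −0.22 to −0.15 in these 6 fits. Over the 22 alternatives the adjusted p ran from 2.1e-05 to 0.79 for the first list and from 0.0015 to 0.79 for the second.

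The ribosomal proteins of the large subunit, a check list of genes expressed at an even level, were higher in 20 of 23 members, by a median of 0.06 (adjusted p = 0.0051 with the preset and 0.79 with an estimated correlation). Rpl7 (0.15), Rplp0 (0.12), Rpl23 (0.12) and Rpl6 (0.08) had the smallest p-values. The call was lost with no filter on dim genes (median 0.06, adjusted p = 0.099) and after median centring (median 0.01, adjusted p = 0.053). It was also lost without Tcl1 tg replicate 1 (median 0.02, adjusted p = 0.18) or CD44ΔB Tcl1 tg replicate 1 (median 0.03, adjusted p = 0.053). The median was 0.09 without both arrays of narrower range. These adjusted p-values lay within a range from 0.00026 to 0.79 over the 22 alternatives.

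Genes of neutrophils, a cell type that a selection for CD5 and CD19 should remove, were higher in 5 of the 6 members above the filter on dim genes, out of 22 on the array, with a median of 1.36 (adjusted p = 0.0079 with the preset and 0.79 with an estimated correlation). S100a8, a granulocyte calcium-binding protein gene, was at 4.57 ± 1.00 in Tcl1 tg and 7.21 ± 2.43 in CD44ΔB Tcl1 tg cells. Its partner S100a9 was at 4.83 ± 0.61 and 7.12 ± 2.07, and the granule protein gene Ngp at 5.33 ± 0.93 and 7.66 ± 1.96. Padi4, also a member, went the other way, at 7.47 ± 1.59 and 5.62 ± 0.52. These 4 genes passed when adjusted over the 6 tested members alone, and 0 over all genes tested. The means of S100a8, S100a9 and Ngp lay below the filter in Tcl1 tg cells, and they passed it through CD44ΔB Tcl1 tg cells. Padi4 did the reverse. The filter thus kept these members for high values in 1 genotype. The median of 1.36 and the adjustment over 6 genes depend on that choice. S100a8 was high in CD44ΔB Tcl1 tg replicates 2 (7.90), 3 (9.67) and 4 (7.38) and not in replicate 1 (3.88). Replicates 2 and 3 are the arrays of narrower range, without which the median was 0.43 and the call was lost (adjusted p = 0.81). It was also lost without replicate 3 alone (median 0.87, adjusted p = 0.068). With no filter on dim genes, 20 of the 22 members were higher, the median was 0.43 and the call was kept. In that fit 48.1% of the 19505 genes were lower, against 59.4% of those above the filter. Genes below the filter, like most members of this list, were thus more often higher in general, and the count of 20 is to be read against that. Over the 21 alternatives the adjusted p ran from 4.1e-06 to 0.81.

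**Figure D3:**
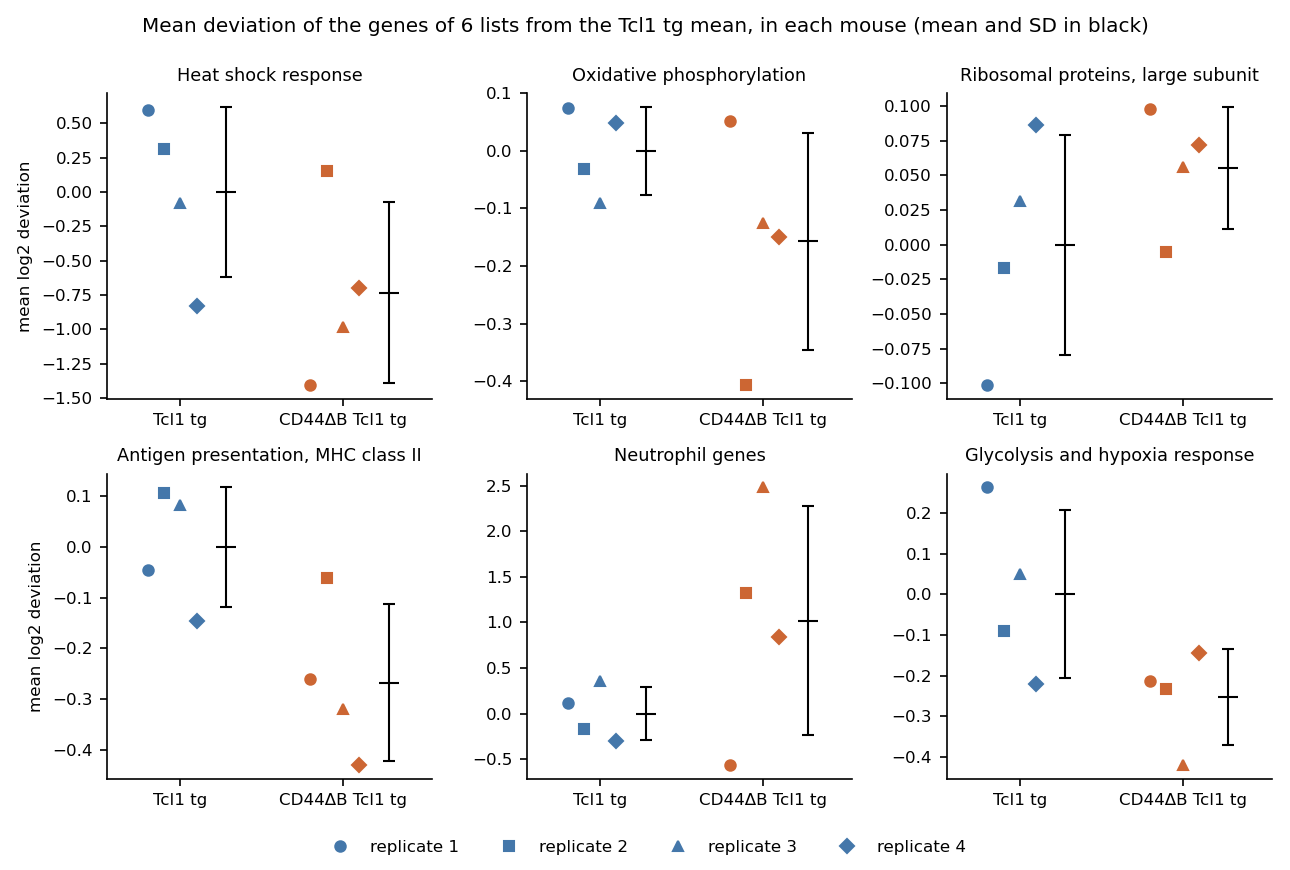
Mean log2 deviation of each list's tested genes from the Tcl1 tg mean (vertical axis) in the 4 Tcl1 tg mice (blue) and the 4 CD44ΔB Tcl1 tg mice (orange), for the 6 lists called with the preset correlation; marker shapes give the replicate number, and black bars the mean and SD. The groups overlap in every panel, and the neutrophil score ranges from −0.57 to 2.48 among the CD44ΔB Tcl1 tg mice.

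The other lists of pathways missed the threshold with the settings fixed in advance, but several passed under other settings on all 8 arrays or without single arrays. Cell cycle genes were lower in 37 of 43 members, with a median of −0.29 (adjusted p = 0.054 with the preset and 0.88 with an estimated correlation). Uhrf1 (−0.54) and Aurka (−0.44) had the smallest p-values. On all 8 arrays this list passed with no filter on dim genes (adjusted p = 0.00010), after quantile normalization (adjusted p = 0.013), with array weights (adjusted p = 0.0075), with the replicate number as a block (adjusted p = 0.031) and on ranks (adjusted p = 0.027). It also passed without Tcl1 tg replicate 3 (median −0.45, adjusted p = 0.00018) or 4 (median −0.32, adjusted p = 0.022). The same held without CD44ΔB Tcl1 tg replicate 1 (median −0.52, adjusted p = 1.6e-06) or 3 (median −0.24, adjusted p = 0.033). The median shrank to −0.05 without CD44ΔB Tcl1 tg replicate 2 (adjusted p = 0.78), to −0.12 without Tcl1 tg replicate 2 (adjusted p = 0.86) and to −0.03 without both arrays of narrower range (adjusted p = 0.97, the highest of its 22 alternatives). MYC targets and ribosome biogenesis genes were lower in 34 of 42 (median −0.12, adjusted p = 0.061), among them Wdr43 (−0.31) and Myc (−0.25). On all 8 arrays they passed with no filter on dim genes (adjusted p = 0.0011), with the block (adjusted p = 0.0499) and on ranks (adjusted p = 0.039), but not with an estimated correlation (adjusted p = 0.79) or fry (adjusted p = 0.53). They also passed without Tcl1 tg replicate 3 (median −0.18, adjusted p = 0.0049) or CD44ΔB Tcl1 tg replicate 4 (median −0.17, adjusted p = 0.033). The median was −0.07 without Tcl1 tg replicate 4 and −0.04 without both arrays of narrower range. Notch pathway genes were higher in 9 of 11 (median 0.08, adjusted p = 0.061), with the target gene Hes5 at 0.36 and the pathway's DNA-binding factor Rbpj at −0.22. They passed with the block (adjusted p = 0.049) and without Tcl1 tg replicate 4 (median 0.09, adjusted p = 0.033), but not with an estimated correlation (adjusted p = 0.79) or fry (adjusted p = 0.53). The median ran from 0.04 without Tcl1 tg replicate 3 to 0.17 without CD44ΔB Tcl1 tg replicate 1.

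The adhesion, hyaluronan and CD44 partner genes were lower in 18 of 25 members (median −0.14, adjusted p = 0.48), with Alcam at 0.54 and Itgb7 at −0.30. Their median ran from −0.17 without CD44ΔB Tcl1 tg replicate 4 to −0.05 without replicate 2 of that genotype. It was −0.07 without the 2 arrays of narrower range. Chemokine and homing receptor genes were lower in 14 of 19 (median −0.18, adjusted p = 0.45), with the CXCL12 receptor gene Ackr3 at −1.13 and Ccr9 at −1.95. Their median ran from −0.26 without Tcl1 tg replicate 1 to −0.09 without Tcl1 tg replicate 2. It was −0.03 without the 2 arrays of narrower range. NF-kB targets were lower in 17 of 25 (median −0.18, adjusted p = 0.39, and 0.024 with a median of −0.29 without Tcl1 tg replicate 2), including Nfkb2 (−0.55) and Traf1 (−0.77). Their median was −0.02 without CD44ΔB Tcl1 tg replicate 3 and 0.04 without the 2 arrays of narrower range. With an estimated correlation their adjusted p was 0.83. Immediate-early genes were lower in 19 of 27 (median −0.18, adjusted p = 0.48, and 0.0011 with a median of −0.32 without CD44ΔB Tcl1 tg replicate 2), including Klf2 (−0.50). Their median was 0.01 without CD44ΔB Tcl1 tg replicate 3, and their adjusted p with an estimated correlation was 0.92. B-cell receptor signalling components (14 of 31 higher, median −0.01, adjusted p = 0.60) included Pik3cd (0.37) and Fyn (0.90). Unfolded protein response genes (17 of 26 higher, median 0.06, adjusted p = 0.37) included Ppp1r15a (−0.75) and Hsp90b1 (0.28). They passed toward higher values without Tcl1 tg replicate 1 (median 0.21, adjusted p = 0.0054) or CD44ΔB Tcl1 tg replicate 4 (median 0.16, adjusted p = 0.013), but not with an estimated correlation (adjusted p = 0.89). Their median was −0.12 without CD44ΔB Tcl1 tg replicate 1. Interferon response genes (12 of 31 higher, median −0.07, adjusted p = 0.73, and 0.029 with a median of 0.05 without Tcl1 tg replicate 3) included Gbp7 (0.54) and Gbp3 (0.47). Their median was −0.20 without Tcl1 tg replicate 2, and their adjusted p with an estimated correlation was 0.93. Wnt and LEF1/TCF targets (5 of 13 higher, median −0.04, adjusted p = 0.98) included Bcl9 (−0.61). Anti-apoptotic genes (12 of 19 higher, median 0.03, adjusted p = 0.45) included Faim (−0.34). Pro-apoptotic genes (12 of 26 higher, median −0.01, adjusted p = 0.39) included Bok (0.32) and Bak1 (−0.32). The medians of the B-cell receptor, interferon and pro-apoptotic lists turned positive after quantile normalization. That of the anti-apoptotic list turned negative after median centring.

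Among the lists of B-cell states, B-1 cell genes were lower in 15 of 26 members (median −0.18, adjusted p = 0.39). This was about the share over all genes tested (59.4%). The median ran from −0.30 without Tcl1 tg replicate 2 to −0.02 without CD44ΔB Tcl1 tg replicate 2. Of the members, 1 (Tppp3) passed when adjusted over the list alone (adjusted p = 0.023) but not over all genes tested. Lgals1, which encodes a galectin, was at −0.91. Plasma cell genes were higher in 14 of 18 (median 0.20, adjusted p = 0.060), with Tnfrsf13b at 0.18 and Irf4 at 0.34. On all 8 arrays the plasma cell list passed with a filter at the 75th percentile (adjusted p = 0.013), after median centring (adjusted p = 0.036), with the block (adjusted p = 0.010) and on ranks (adjusted p = 0.030), but not with an estimated correlation (adjusted p = 0.83) or fry (adjusted p = 0.94). It also passed without Tcl1 tg replicate 1 (median 0.34, adjusted p = 0.0026) or 4 (median 0.21, adjusted p = 0.040). The same held without CD44ΔB Tcl1 tg replicate 2 (median 0.39, adjusted p = 0.00076) or 4 (median 0.34, adjusted p = 0.012), and without both arrays of narrower range (median 0.57, adjusted p = 0.0010). It had a median of −0.20 without CD44ΔB Tcl1 tg replicate 1 (adjusted p = 0.35) and of 0.03 without Tcl1 tg replicate 2 (adjusted p = 0.58). Follicular B-cell genes (12 of 18 higher, median 0.04, adjusted p = 0.73) included Il4ra (−0.50). Germinal centre genes (6 of 11 higher, median 0.03, adjusted p = 0.98) included Plxnb2 (−1.19) and Mybl1 (−0.83). Both medians were negative after median centring.

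Of the other cell types, stromal and endothelial genes (4 of 6 higher, median 0.15, adjusted p = 0.060) included Col1a1 (0.40) and Col4a1 (0.23). They passed with array weights (adjusted p = 0.039), and without Tcl1 tg replicate 4 (median 0.21, adjusted p = 0.040) or CD44ΔB Tcl1 tg replicate 1 (median 0.19, adjusted p = 0.024), but not with an estimated correlation (adjusted p = 0.79) or fry (adjusted p = 0.53). Their median was 0.08 without Tcl1 tg replicate 1 and 0.02 without the 2 arrays of narrower range. Platelet genes (4 of 5 higher, median 0.17, adjusted p = 0.14) included Pf4 (0.21) and Itga2b (0.25), and had a median of −0.03 without the 2 arrays of narrower range. Dendritic cell genes (2 of 7 higher, median −0.21, adjusted p = 0.39) included Tcf4 (−0.28). Over all 16 on the array their median was −0.02. The list scores of the 7 did not overlap between the genotypes (exact permutation test, two-sided, p = 0.0286, and 0.48 adjusted by Benjamini-Hochberg over the lists). The median of the 7 ran from −0.25 without CD44ΔB Tcl1 tg replicate 3 to −0.12 without replicate 1 of that genotype. Macrophage genes (3 of 8 higher, median −0.17, adjusted p = 0.84) included Adgre1 (−1.09) and Fcgr1 (0.22) and had a median of 0.20 without the 2 arrays of narrower range. Erythroid genes (4 of 8 higher, median −0.09, adjusted p = 0.89) included Xk (−0.85) and Klf1 (0.31). The T cell list had 3 members above the filter, among them Icos (0.40) and Lat (0.27). The NK cell list had 0 and the sex-linked list 1, Eif2s3y (0.01). These 3 were not tested as lists. The mean, the median and the direction of the test differed in sign in the B-cell receptor, interferon, macrophage, erythroid, pro-apoptotic, anti-apoptotic, follicular and germinal centre lists.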

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

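The tests of the 3 patterns weighed here were written down before their results, except 3: for the sterol genes, the one on Y-linked genes and the one mouse by mouse against genes of like level, and for the neutrophil genes, the one on all list members. The 7 neutrophil genes were picked after S100a8, S100a9, Ngp and Padi4 had been seen. The list of sterol genes was drawn up after 3 of its members had been seen, and the repeats without those 3 genes and without the 2 arrays of narrower range were chosen after the data had been seen. Of the 35 splits of the 8 arrays into 4 and 4, 22 had at least the 6 lists of the real split (highest other 10), so chance cannot be excluded for the count of lists. At least 1 gene past the adjusted threshold was found in 8 of the 35 (highest other 4), so chance cannot be excluded for a count of 1 as such. This count does not bear on Cd44, which was called in the real split and in 0 of the others. Its difference of 2.66 was reached in 1 split, the real one (highest other 1.54). The gene called when Tcl1 tg replicates 1 and 4 with CD44ΔB Tcl1 tg replicates 2 and 4 were set against the rest was the Y-linked Eif2s3y.

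At an unadjusted p under 0.05, more genes were lower (482) than higher (145) in CD44ΔB Tcl1 tg cells. Chance is not excluded, since 7 of the 35 splits had as many genes in 1 direction, up to 701. The share of lower genes, 76.9% in the deposited values, was 57.6% after quantile normalization and 59.1% without the 2 CD44ΔB Tcl1 tg arrays of narrower range, so the range of these arrays may account for much of the surplus. With no filter on dim genes the counts were 608 lower and 553 higher (52.4% lower). With a filter at the 75th percentile 86.4% were lower, and after median centring 583 were lower and 103 higher (85.0% lower). Why these 2 arrays are narrower stays open, and they are also the 2 arrays with the highest neutrophil levels. A difference between the genotypes was not tested apart from these and also stays open.

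Genes of sterol synthesis were lower in CD44ΔB Tcl1 tg cells in all 19 members tested of 25 listed, with a median log2 difference of −0.39 and, for example, Msmo1 at −0.78, Idi1 at −0.84 and the regulator Srebf2 at −0.39. No member passed over all genes (adjusted p = 0.76 or higher), and 5 passed when adjusted over the list alone. The list's unadjusted p was 0.039 by camera with an estimated correlation and 0.011 by fry, in limma. Without the 3 genes that prompted the list these were 0.047 and 0.014, and 0 of the other 16 passed over the list alone (smallest adjusted p 0.060). Of the 35 splits 1, the real one, gave a mean difference as large (0.476, highest other 0.450), and without the 3 genes that prompted the list this was also 1 split (0.438, highest other 0.415). The sterol genes are correlated with each other (estimated at 0.41, and at 0.37 among the 16). Leaving out the 3 thus does not undo the choice of the list on these same mice, here or below. The narrower arrays may account for part of the lower sterol genes but not for all of it. The median was −0.34 after quantile normalization and −0.29 without these arrays, which leaves 2 mice in that group, against −0.39 as deposited. All 19 genes were lower in both repeats. Against the surplus of lower genes, the median lay at percentile 0 of 10000 random lists of genes of like level (lowest −0.28), but such lists lack the correlation between the sterol genes (estimated at 0.41). Weighed mouse by mouse, and without the 3 genes that prompted the list, genes of like level differed by −0.07 and the other 16 sterol genes by −0.44. After subtraction −0.37 was left (SE 0.12), as large in 1 of the 35 splits, the real one (highest other 0.351). The surplus among genes of like level was thus smaller than the difference of the sterol genes. A list drawn up for low values in these mice would stand out from the surplus in any case, so the rank among the splits cannot decide this. The Y-linked genes argue against sex as the cause, since both genotypes held mice with high and with low levels of them. With high or low Kdm5d and Uty as a term, the difference between the genotypes in the mean over the genes was −0.47 (SE 0.15). With Eif2s3y instead it was −0.48 (SE 0.15), but each genotype then held 2 high mice, so that term could not change the difference. High and low mice themselves differed by −0.03 (SE 0.16) by Kdm5d and Uty and by 0.00026 (SE 0.15) by Eif2s3y. The groupings place CD44ΔB Tcl1 tg replicate 1 differently, so the sex of that mouse is not settled. A lower expression of these genes with the CD44ΔB alteration is thus a hypothesis, found and tested on the same 8 mice, and other differences between the mice that the labels do not give stay open.

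Of 7 neutrophil genes (S100a8, S100a9, Ngp, Camp, Ltf, Lcn2 and Retnlg), the mean over the genes was 6.92, 8.80 and 6.45 in CD44ΔB Tcl1 tg replicates 2, 3 and 4, 4.39 in replicate 1, and 4.43 to 5.55 in the Tcl1 tg mice. The genes went up and down together over the 8 arrays, with a median correlation over the 21 pairs of r = 0.939 (Spearman's rho 0.833, permutation p = 0.001, the smallest that 1000 shuffles give) and of 0.873 without CD44ΔB Tcl1 tg replicates 2 and 3. Genes picked for a rise in the same group correlate in part for that reason, and these shuffles do not allow for it. Over all 22 list members on the array, with the genotype means taken out, the median correlation was 0.546 (shuffles within genotypes, p = 0.001). The shuffles move each gene on its own, so they cannot tell neutrophil RNA from a shift common to the dim genes of an array. Of the 22 members, 6 lay above the filter on dim genes, and lists of other dim genes were not compared. The joint rise of the 7 genes is what RNA of neutrophils left after the selection for CD5 and CD19 could give. Padi4, another gene of the list, was however higher in Tcl1 tg cells (7.47 against 5.62). A chance distribution of such mice over the groups is not excluded, since 5 of the 35 splits gave a difference as large (1.84, highest other 2.42). A larger number of neutrophils in the spleens of CD44ΔB Tcl1 tg mice was not tested and stays open.

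Single mice stood apart from the other 3 of their group in 15 of 266 groups of 4 values, where chance gives 13.3 (about 1 in 20). Among genes, these were in Tcl1 tg mice Mcl1 in replicate 1 (12.22 on the log2 scale), Alcam (9.12) and Aldoa (11.03) in replicate 2, Ngp in replicate 3 (6.71), and Hspa1b (10.96) and Bcl9 (6.91) in replicate 4. In CD44ΔB Tcl1 tg mice they were Alcam (9.84), Irf4 (10.66), Icos (8.57) and Col4a1 (6.57) in replicate 1 and Il4ra (8.99) in replicate 4. Among list scores, they were the adhesion list in CD44ΔB Tcl1 tg replicate 2 (−0.27), the chemokine receptor list in CD44ΔB Tcl1 tg replicate 3 (−0.60) and the germinal centre list in Tcl1 tg replicate 1 (0.18). Among array measures, it was the interquartile range of Tcl1 tg replicate 4 (3.76).

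The cre hybridization control, which no comparison used, read 13.34 ± 0.04 on the Tcl1 tg arrays and 13.45 ± 0.05 on the CD44ΔB Tcl1 tg arrays (SD, n = 4), a difference of 0.11 with no overlap (exact permutation test, two-sided, p = 0.0286, and 0.371 adjusted by Benjamini-Hochberg over 13 array measures).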

How the results depend on the processing

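The fit without the 2 CD44ΔB Tcl1 tg arrays of narrower range was chosen after the data had been seen. Cd44 kept its direction under all 19 alternatives and passed in 18. Without those 2 arrays it was −2.66 (adjusted p = 0.11, range over the alternatives 0.00021 to 0.11), with fewer arrays in the fit. The count of genes was 168 at an unadjusted p under 0.05 with a 1.5-fold difference, a looser threshold, and 0 without the 2 arrays (limma, 362 at an unadjusted p under 0.05). The count of lists was 10 with the replicate number as a block, 0 with an estimated correlation and 0 with fry. No label says that the replicate numbers pair the mice. The correlations of deviations within numbers were 0.097, 0.103, −0.01 and −0.16, and 3 of the 8 arrays went best with their own number. These values give no sign of a pairing but cannot exclude one. Number 1 joined mice of 351 and 352 days and number 3 mice of 275 and 276 days. Numbers 2 and 4 joined mice of 318 and 456 and of 421 and 270 days. Of the comparisons of lists, 500 kept direction and side of the threshold, 32 gained a call, 32 lost one and 44 reversed. Of those of the 89 named genes other than Cd44, 1637 kept both and 17 reversed, with 0 past the threshold (lowest adjusted p 0.086).

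The reversals below are log2 differences or list medians. With no filter on dim genes, the pro-apoptotic list was at 0.027, Wnt 0.098, germinal centre −0.018, macrophage 0.21 and erythroid 0.15. After quantile normalization, the B-cell receptor list was at 0.039, pro-apoptotic 0.052 and interferon 0.0050. After median centring, Bcl2 was at −0.0041, Eif2s3y −0.029, and the anti-apoptotic list −0.017, follicular −0.0068 and germinal centre −0.016. With array weights, Eif2s3y was at −0.38, pro-apoptotic 0.0057 and unfolded protein response −0.0041. Without the 2 arrays, Cd5 was at 0.058, Mki67 0.11, Lat −0.055 and Itga2b −0.011. In the same fit the NF-kB list was at 0.041, pro-apoptotic 0.042, Wnt 0.0090, germinal centre −0.15, macrophage 0.20 and platelet −0.025. These 26 reversals were of results that passed no threshold, and the cause was not tested.

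Leaving out each array in turn, Cd44 ranged from −2.76 to −2.49, the count of genes from 1 to 2 and the count of lists from 4 to 10. Values that crossed 0 ranged from −0.12 to 0.16 for Bcl2, −1.10 to 1.21 for Eif2s3y, −0.37 to 1.24 for Icos and −0.71 to 0.057 for Mki67. List medians that crossed 0 ranged from −0.060 to 0.091 (anti-apoptotic), −0.045 to 0.027 (pro-apoptotic), −0.037 to 0.078 (follicular) and −0.46 to 0.25 (macrophage). Others ranged from −0.12 to 0.21 (unfolded protein response), −0.18 to 0.038 (germinal centre), −0.20 to 0.047 (interferon, which passed without Tcl1 tg replicate 3) and −0.20 to 0.39 (plasma cell). The last ranged from −0.16 to 0.037 (erythroid), −0.14 to 0.045 (Wnt) and −0.32 to 0.012 (immediate-early). The fit without immunoglobulin and T cell receptor segments was not run, since the annotation names no such gene. The separation of positive from negative control probe sets was weakest on the 2 arrays of narrower range.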

Other observations

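The test on genes near Cd44 was chosen only after the result was seen. Of 41 genes tested within 10 Mb of Cd44 in the gene table of assembly GRCm38.p6, 30 were lower in CD44ΔB Tcl1 tg cells, and 4 of the 41 had an unadjusted p under 0.05 in limma. Over all genes tested, 59.4% were lower, and 627 of 10001 had an unadjusted p under 0.05. A segment carried along with the altered Cd44 gene is a candidate explanation for differences near Cd44. The median of the 41 genes, −0.10, lay at percentile 16.2 of 9197 runs of as many neighbouring genes (median of runs −0.05). The median size of their differences, 0.15 in either direction, lay at percentile 57.5 of the runs. The median size of the runs was 0.14. Neither the direction nor the size of the differences lay outside the bulk of the runs. These values thus do not point to such a segment, which stays open.

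The Y-linked genes Kdm5d, Uty and Eif2s3y were read in mice whose sex the labels do not give. In Tcl1 tg replicates 1 and 4 Kdm5d was at 6.60 and 7.01, Uty at 6.89 and 7.28 and Eif2s3y at 9.09 and 9.30, and in replicates 2 and 3 Kdm5d was at 3.52 and 2.59, Uty at 3.03 and 2.15 and Eif2s3y at 3.48 and 3.41. In CD44ΔB Tcl1 tg replicates 2 and 4 Kdm5d was at 6.99 and 7.35, Uty at 7.84 and 8.03 and Eif2s3y at 9.62 and 9.69, and in replicate 3 they were at 2.82, 2.72 and 2.76. In CD44ΔB Tcl1 tg replicate 1 Kdm5d was at 6.97 and Uty at 7.84, while Eif2s3y was at 3.28.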
